A study of Gossypium barbadense and Gossypium hirsutum with 8 samples.

How the data were processed

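Gene expression was measured in cotton fibre collected 10 days after flowering (10 days post anthesis, in rapid elongation) on Affymetrix cotton arrays. There were 8 arrays: 3 high-yielding and 3 low-yielding backcross inbred lines (BILs, inbred lines from backcrosses between 2 cotton species) and the 2 parents, SG747 (Gossypium hirsutum, high-yielding) and Giza75 (G. barbadense, low-yielding), with 1 array each. Per the labels' protocols, total RNA from fibre stripped off the ovules was labelled with biotin from 10 micrograms of RNA. The deposited values are intensities on a linear scale, 1 per probe set; the submitters' processing notes name GCOS and MAS5, and no version or scaling target is given in the sources used here. The design text and the sample labels give the line names of high-yield BILs 1 and 3 the opposite way round, which leaves the groups as they are.

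The table held 24132 probe sets, of which 103 were Affymetrix control probe sets, leaving 24029. All 8 columns of the table were used, each matched to its sample by the sample's own identifier. No 2 arrays held identical values: at most 1.20% of the values were equal in any pair of arrays. The deposited intensities were kept as they stood and transformed as log2(value + 16), so that a fold change understates the change of probe sets with low values. The 40% of probe sets with the lowest mean were left out, which left 14417 for each test. The fits used lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count took probe sets with an unadjusted p under 0.05 and at least a 2-fold difference. Plots were drawn with matplotlib.

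The comparisons were high-yield against low-yield BILs (3 against 3), all high-yielding against all low-yielding plants with the parents (4 against 4), and the parents against each other without a test. For each BIL a position between the parents was computed as the slope of its deviation from the mid-parent value on the parental half-difference, over probe sets at least 4-fold apart between the parents, so that 1 is the high-yield parent and -1 the low-yield parent. The BIL contrast was also correlated with the parental contrast across probe sets. Single values of the BIL groups were compared by an exact two-sided permutation test, for which 3 against 3 cannot go below 0.1. Each line had 1 array, so the spread within a group holds differences between lines and between sample preparations and arrays together. The design cannot tell these apart, and p-values measure no more than that joint spread. The number of arrays limits the precision.

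Probe sets were to be named by a rule written before the data were examined: the largest changes past the threshold with non-overlapping groups, filled up in order of unadjusted p where too few passed, and for the parents the largest differences among probe sets above the median. Of the probe-set identifiers, 0 matched the 74561 genes of the reference table used here (a G. barbadense annotation), and the files do not pair them with gene names. The same rule then allowed 2 probe sets higher and 2 lower per contrast, which are called probe sets A to H, J and K in the text in place of their array identifiers, and none of the 23 gene lists fixed beforehand was tested.

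The fits were tested on simulated data made from the arrays' own levels and fitted variances with independent normal noise, with 200 probe sets changed. For the 6 BIL arrays, with 50 probe sets per fold, limma recovered 0% of the 2-fold and 42% of the 4-fold changes. It recovered 80% of the 8-fold and 100% of the 16-fold changes. With the levels and variances of the quantile-normalized arrays the shares were 8%, 88%, 98% and 100%. The simulated values themselves were not normalized, so the normalization was not tested. For the 8 arrays on the deposited values the shares were 10%, 70%, 96% and 100%. The simulated noise left out variation shared across an array, so these shares need not hold for the real arrays. With no change simulated, 4.90% of probe sets had a p under 0.05 in the 6-array fit and 0 passed the adjusted threshold.

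Alternatives set before the data were examined were pseudocounts of 1 and 64, no filter, leaving out the lowest 60%, quantile normalization, no intensity trend, leaving out probe sets marked as shared between transcripts (_s_at and _x_at), leaving out each array, the line number as a block, all 8 arrays with a parent term, and an 8-fold parental difference. Median centring, cyclic loess, scaling to the bacterial poly-A spikes (RNAs added to a sample before labelling; 36 probe sets), the spike level as a covariate, and quantile normalization combined with leaving out arrays or with the 8-fold difference were added after seeing the data. The hybridization spikes (27 probe sets) are labelled RNAs added before hybridization.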

Results

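Transcript levels in elongating cotton fibre were compared between high-yielding and low-yielding inbred lines of a cross between G. hirsutum and G. barbadense and between the parents of the cross. There were 3 high-yield BILs, 3 low-yield BILs and 1 array of each parent, all at 10 days post anthesis. The design names differential expression between the high-yield and low-yield lines as its question.

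The arrays differed in brightness, more at low than at high signals. Median signals were 13.5, 26.0 and 15.7 in high-yield BILs 1, 2 and 3, and 36.3, 30.5 and 13.2 in low-yield BILs 1, 2 and 3. The high-yield parent had a median of 22.3 and the low-yield parent 17.0, so the highest median was 2.75-fold the lowest. Higher up the scale the arrays lay closer: 1.89-fold for the mean signal, 1.63-fold for the 99th percentile and 1.41-fold for the highest signal. The group means of the medians were 18.4 ± 6.67 (SD, n = 3) in high-yield and 26.7 ± 12 (SD, n = 3) in low-yield BILs. That difference lay within the spread inside the groups (exact permutation test, two-sided p = 0.4). The median log2 difference over all tested probe sets was -0.28 between high-yield and low-yield BILs and 0.04 after quantile normalization, and each difference on the deposited values stands against that shift. The poly-A spikes, RNAs added before labelling, were lower on brighter arrays (Pearson r = -0.87, exact permutation p = 0.0088, adjusted p = 0.0176 over 4 relations; Spearman rho = -0.79, exact permutation p = 0.0279, adjusted p = 0.0559; r = -0.74 without low-yield BILs 1 and 2, the arrays farthest from the middle). The share of the summed signal in the brightest 1% of probe sets, 22.8% to 31.3%, was also lower on brighter arrays (Pearson r = -0.93, exact permutation p = 0.0037, adjusted p = 0.0147; Spearman rho = -0.86, exact permutation p = 0.0107, adjusted p = 0.0429; r = -0.90 without the same arrays). That share is divided by the summed signal, which was itself higher on brighter arrays, so part of this relation is built in. The hybridization spikes, added later, ranged 1.40-fold over the 8 arrays. Their Pearson r with the median was 0.51 (exact permutation p = 0.196, Spearman rho = 0.45), which leaves a relation open.

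**Figure D1:**
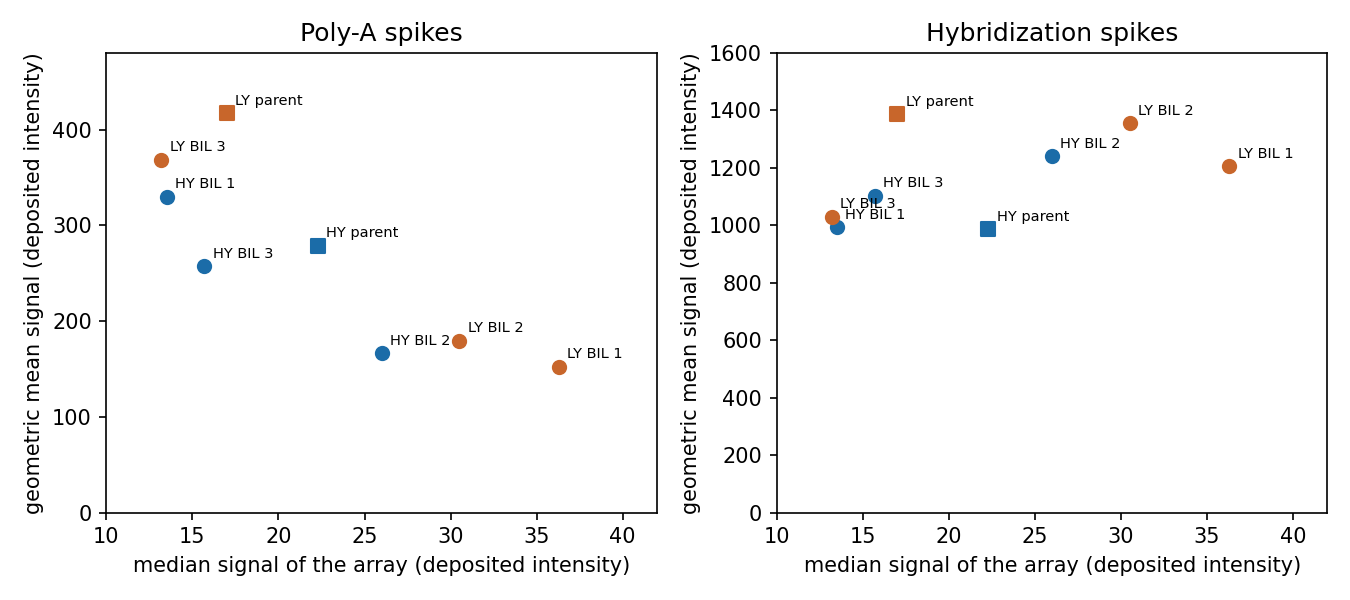
Geometric mean signal of the poly-A spikes (left) and of the hybridization spikes (right) against the median signal of each array, both as deposited intensity on linear axes. Blue marks high-yielding and orange low-yielding plants, circles BILs and squares parents, 1 point per array; the poly-A spikes range from 152 in low-yield BIL 1, which has the highest median, to 417 in the low-yield parent.

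Between high-yield and low-yield BILs, probe set A had a mean signal of 30.4 ± 15.1 (SD, n = 3) in the high-yield and 6.10 ± 1.61 in the low-yield lines, a log2 difference of 1.02 ± 0.31 (SE). Probe set B had 61.9 ± 19.6 against 21.3 ± 16.6 (log2 difference 1.14 ± 0.47). In the other direction, probe set C had 4.80 ± 1.61 in the high-yield and 29.9 ± 4.85 in the low-yield lines (log2 difference -1.14 ± 0.26), and probe set D 10.0 ± 10.0 against 76.8 ± 51.7 (log2 difference -1.71 ± 0.53). These 4 probe sets were picked among those with non-overlapping groups on the deposited values, and the groups stayed apart with quantile normalization. For probe set D the nearest lines were high-yield BIL 1 at 21.4 and low-yield BIL 3 at 23.3. None of the 4 passed the adjusted threshold (limma, adjusted p = 0.999 each). Their signals were low, and the log2 differences of A, B, C and D were 2.07, 1.89, -2.44 and -2.93 with a pseudocount of 1 and 0.42, 0.57, -0.45 and -0.86 with a pseudocount of 64. The difference of probe set B also rested on 1 array: it was 0.75 without low-yield BIL 2 (0.92 against 1.38 with quantile normalization). The parents lay in the same order as their lines for the first pair: 16.4 in the high-yield and 2.60 in the low-yield parent for probe set A, and 51.7 and 0.5 for probe set B. For the other pair the parents lay the opposite way, with 44.8 in the high-yield and 11.7 in the low-yield parent for probe set C and 80.1 and 19.1 for probe set D.

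Over the array, 0 of 14417 probe sets passed an adjusted p of 0.05 between the BIL groups in limma, with the deposited values and with quantile normalization, and 139 (0.96%) and 311 (2.16%) had an unadjusted p under 0.05. These shares lay below the 4.90% and 4.99% of simulated data with no change and independent noise. At an unadjusted p under 0.05 and 2-fold there were 99 probe sets, 2 higher and 97 lower in the high-yield lines. With quantile normalization there were 101, 14 higher and 87 lower, of which 45 were shared with the 99. The groups did not overlap for 386 probe sets (2.68%), or 903 (6.26%) with quantile normalization, where chance gives 10%. The count of 99 rested on single arrays: it was 14 without high-yield BIL 1, 627 without BIL 2 and 24 without BIL 3, and 7 without low-yield BIL 1 and 3138 without low-yield BIL 3, with 0 past the adjusted threshold each time.

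**Figure D2:**
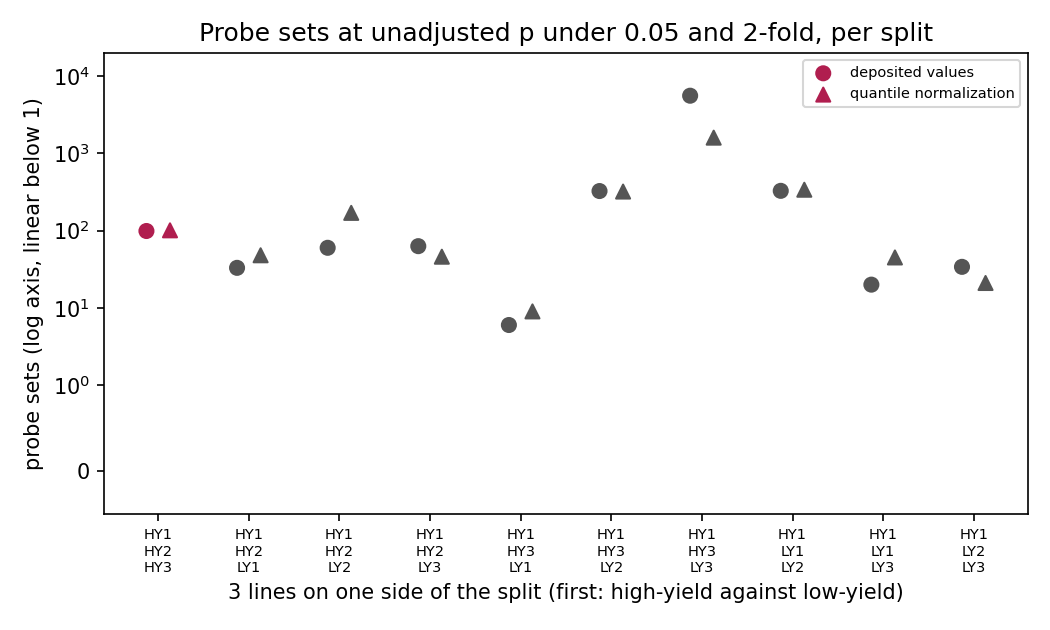
Number of probe sets at an unadjusted p under 0.05 and 2-fold (log axis, linear below 1) for each of the 10 ways to split the 6 BILs into 3 and 3, on deposited values (circles) and with quantile normalization (triangles). Each label gives the 3 lines on one side; the split by yield (red, first) has 99 and 101, and the highest, high-yield BILs 1 and 3 with low-yield BIL 3 against the others, has 5596 and 1602.

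With each parent added to the lines of its yield class, probe set E had a mean signal of 110 ± 39.7 (SD, n = 4) in the high-yielding and 398 ± 143 in the low-yielding plants (log2 difference -1.70 ± 0.41 SE). Probe set F had 465 ± 115 against 1115 ± 240 (log2 difference -1.24 ± 0.32). On the higher side stood probe set A, with 26.9 ± 14.2 against 5.22 ± 2.19, and probe set B, with 59.4 ± 16.8 against 16.1 ± 17.1. None of the 4 passed the adjusted threshold (limma, adjusted p = 0.9996 each), and the groups of probe sets E and F overlapped after quantile normalization. The log2 differences of A and B, 0.97 and 1.37, were 2.12 and 2.70 with a pseudocount of 1 and 0.38 and 0.64 with 64. In all, 0 of 14417 probe sets passed an adjusted p of 0.05 in limma and 381 (2.64%) had an unadjusted p under 0.05, where simulated data with no change gave 4.93%. With quantile normalization there were 0 and 862 (5.98%, against 5.41%). At an unadjusted p under 0.05 and 2-fold there were 232, 17 higher and 215 lower in high-yielding plants, and 221 with quantile normalization, 48 higher and 173 lower, with 158 shared. The parents are of different species, so this contrast holds part of the species difference. The count of 232 was 108 without the high-yield parent, 120 without high-yield BIL 1, 559 without high-yield BIL 2, 123 without low-yield BIL 1 and 696 without low-yield BIL 3.

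The parents had 1 array each, so their differences carry no error estimate. They are of different species, and whether the probes match both equally was not tested. A low signal in 1 parent therefore need not mean a low transcript level. The same limit holds for each result that rests on the parental difference. Among the largest, probe set G had a signal of 1713 in the high-yield and 1.2 in the low-yield parent, and probe set H 1870 and 5.60. In every BIL both were high: 346 to 1615 for probe set G and 875 to 1383 for probe set H. Probe set J had 82.0 in the high-yield and 2786 in the low-yield parent, with 134, 607 and 226 in high-yield BILs 1, 2 and 3 and 1036, 154 and 1318 in low-yield BILs 1, 2 and 3. Probe set K had 60.2 and 1950 in the parents, with 226, 415 and 130 in the high-yield and 616, 233 and 848 in the low-yield lines. The median log2 difference between the parents over all tested probe sets was 0.42, and 0.03 with quantile normalization. Counts on the deposited values stand against that shift. At least 2-fold, 3100 probe sets were higher and 619 lower in the high-yield parent, and at least 4-fold, 416 and 111. With quantile normalization the counts were 1232 and 1308, and 208 and 196.

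Across the 527 probe sets at least 4-fold apart between the parents, most lines lay on the side of the high-yield parent. The positions, where 1 is the high-yield and -1 the low-yield parent, were 0.44, 0.64 and 0.42 in high-yield BILs 1, 2 and 3 and 0.49, 0.79 and -0.06 in low-yield BILs 1, 2 and 3. Of the 527, 416 were higher and 111 lower in the high-yield parent. A brighter array therefore moves a line toward that parent on the deposited values. With quantile normalization (404 probe sets) the positions were 0.73, 0.57 and 0.62, and 0.27, 0.71 and 0.14. A slope close to the mid-parent value need not mean that a line lay midway for most probe sets. With quantile normalization low-yield BIL 3 was nearer the high-yield parent for 79.8% of probe sets higher in that parent. For those higher in the low-yield parent the share was 21.9% (37.5% and 39.6% on the deposited values). Low-yield BIL 1 had 84.6% and 51.0% (92.1% and 28.8%), and the other lines at least 73.5% with quantile normalization. The group means were 0.50 ± 0.12 (SD, n = 3) and 0.41 ± 0.43, a difference within the spread inside the groups (exact permutation test, two-sided p = 0.9). With quantile normalization they were 0.64 ± 0.08 and 0.37 ± 0.30 (exact permutation test, p = 0.3). The smallest p this design allows is 0.1. Without low-yield BIL 3 the difference of 0.09 turned to -0.14, and without low-yield BIL 2 it was 0.28.

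**Figure D3:**
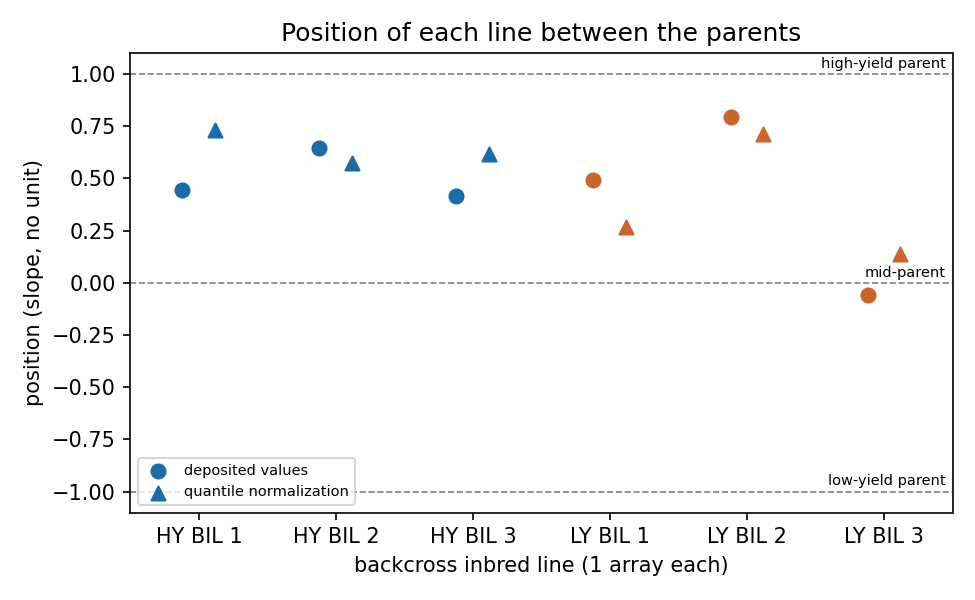
Position of each BIL between the parents, as a slope without unit, for 3 high-yield lines (blue) and 3 low-yield lines (orange), 1 array each, on deposited values (circles) and with quantile normalization (triangles). Dashed lines mark the high-yield parent at 1, the mid-parent value at 0 and the low-yield parent at -1; low-yield BIL 3 lies lowest, at -0.06 and 0.14.

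The log2 differences between the BIL groups and between the parents had a Pearson r of 0.24 across probe sets, which are not independent replicates, and 0.25 with quantile normalization. The 2 contrasts share no array. With no filter on low values it was 0.10, without low-yield BIL 3 it was -0.03, without low-yield BIL 2 it was 0.45 and without high-yield BIL 2 it was 0.14.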

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

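The tests of explanations in this part were chosen after the results were seen. In all, 42 groups of 4 arrays were examined: each yield class with its parent, for the array measures and the named probe sets. Of these, 6 had an array far from the other 3. The rule marks about 1 in 20 independent groups by chance, but that rate cannot be set against the 6. The named probe sets were picked from these same data, probe set H for its parental difference, and some array measures are related. AFFX-Gra-actin-M, a control probe set, had a signal of 965 in the low-yield parent and 178 to 270 in the low-yield BILs, and AFFX-Gra-actin-3 had 615 against 157 to 233. Probe set H was at 5.60 in the low-yield parent and 875 to 979 in the low-yield BILs. Probe set C was at 44.8 in the high-yield parent and 3.10 to 6.30 in the high-yield BILs. Probe set B was at 84.4 in high-yield BIL 3 and 48.0 to 53.4 in the other high-yielding plants. The highest signal on the array was 15508 in high-yield BIL 2 and 12008 to 12308 on the other high-yield arrays.

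The array medians differed 2.75-fold. A difference in scanner or hybridization gain would move the hybridization spikes with the median. Their slope on it was 0.18 ± 0.10 (jackknife SE, log2 scale) where gain alone gives 1, which argues against gain as the whole cause of the differing medians. The medians lay near background and the spikes at 987 to 1387, so a part for gain at higher signals stays open. The poly-A spikes fell as the median rose (Pearson r = -0.87, exact permutation p = 0.0088), as a different balance of sample RNA against spike at labelling could give. A few probe sets taking more of the signal on dimmer arrays stays open. The share of the brightest 1% had r = -0.93 with the median, but its divisor, the summed signal, differed 1.89-fold between arrays, so this r cannot decide. RNA integrity stays open as well: the 5'/3' signal ratio of the control ss1 had r = 0.72 with the median (exact permutation p = 0.05, adjusted p = 0.0667). No biological explanation was tested.

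Among the 10 ways to split the 6 BILs into 3 and 3, the yield groups gave 0 probe sets past the adjusted threshold, while high-yield BILs 1 and 3 with low-yield BIL 3 against the others gave 8383. That split parts the dimmer arrays from the brighter and points to a structure of the samples other than yield. Overall scale may explain part of it: on the deposited values 8320 of the 8383 were higher on the brighter arrays, while with quantile normalization 2729 passed, 1369 higher and 1360 lower, of which 1431 were among the 8383 in the same direction and 1298 were not. At most 1 passed for any other split after that normalization. Those counts cannot test scale, since what the normalization leaves of a brightness difference would show mainly in this split. Whether a common scale is the whole cause stays open. RNA integrity cannot be told apart from it: the 5'/3' ratio of ss1 was at least 0.324 on the brighter and at most 0.271 on the dimmer BIL arrays and that of ubq11 at least 0.481 against at most 0.381, but that of actin overlapped (0.157 to 0.174 against 0.124 to 0.217), and the parents lay in the other order for ss1 (0.211 for the brighter and 0.345 for the dimmer) and ubq11 (0.484 and 0.584), with differences between the lines or in fibre stage open as untested.

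Low-yield BIL 2 lay nearer the high-yield parent than low-yield BILs 1 and 3 did. Exchanged labels between the groups cannot be told apart from a difference between lines. The lowest high-yield position with quantile normalization, 0.57 in high-yield BIL 2, lay above the 0.27 of low-yield BIL 1. That gap was less than 2 SDs of the low-yield lines (SD 0.30, n = 3). The SD includes low-yield BIL 2, the line in question, so this bar cannot decide. The split that sets low-yield BIL 2 with high-yield BILs 1 and 3 gave 326 probe sets at an unadjusted p under 0.05 and 2-fold (321 with quantile normalization). The yield groups gave 99 (101), but high-yield BIL 1 with low-yield BILs 1 and 2 gave 328 (339). With the parents, 29 probe sets lay in the way of the first split against 2 for the yield groups. These come from the 404 probe sets that gave the positions, so they are no separate support. None of these counts can decide on an exchange, and a single wrong label is open too. Overall scale as the whole cause would close the gap between low-yield BILs 2 and 3, which was 0.85 on the deposited values and still 0.57 with quantile normalization. A different share of the genome from each parent is a biological explanation that was not tested.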

How the results depend on the processing

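Median centring, cyclic loess, the poly-A settings and quantile normalization combined with another change were chosen after seeing the data, as was leaving out lines for the position; the other alternatives were planned. In limma, 0 probe sets passed the adjusted threshold between the BIL groups under each alternative but the replicate block, which gave 8 (lowest adjusted p 0.0098; 0.1 to 1 under the others), and 0 passed with the parents except with the poly-A covariate, which gave 40 (and 0 with quantile normalization); the cause was not tested. The line numbers do not pair the lines: same-numbered lines deviated together with r = -0.29, 0.21 and 0.58. The gene list alternatives were not run, as no list could be matched.

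The 99 probe sets at an unadjusted p under 0.05 and 2-fold between the BIL groups became 42 with a pseudocount of 64, 43 without the lowest 60% and 47 without probe sets marked as shared (fewer were tested in these last settings), 11 scaled to the poly-A spikes, 220 with the poly-A covariate, 448 with the replicate block and 203 with all 8 arrays and a parent term. Leaving out 1 array gave 7 (without low-yield BIL 1) to 3138 (without low-yield BIL 3), and with quantile normalization, where the count was 101, 24 to 765 for the same arrays, with 411 without high-yield BIL 2, 48 without high-yield BIL 3 and 269 without low-yield BIL 2. With the parents, 232 became 107 with a pseudocount of 64, 84 without shared probe sets, 54 scaled to the poly-A spikes and 450 with the poly-A covariate. Leaving out 1 array gave 108 (without the high-yield parent) to 696 (without low-yield BIL 3), and 113 to 441 (without low-yield BIL 2) with quantile normalization. The other alternatives stayed within 1.5 times. Median centring gave 21 higher and 65 lower between the BIL groups, and 68 and 153 with the parents. The cause of these changes was not tested. The log2 differences of the named probe sets A to D between the BIL groups, and of A and B with the parents, moved by over 1.5 times with either pseudocount, and lay between -2.93 and 2.70 with a pseudocount of 1 and between -0.86 and 0.64 with 64. Between the BIL groups, the log2 difference of C, -1.14, was -0.74 with median centring (cause not tested). With a parent term, it was -0.57, and that of D, -1.71, was -0.92. The parents lay the opposite way for both. Of the probe sets named in these contrasts, E passed with the poly-A covariate (limma, adjusted p = 0.0385; 0.138 to 1 under its other alternatives).

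Between the parents, the 3100 higher and 619 lower at 2-fold became 1695 and 293 with a pseudocount of 64, 1232 and 1308 with quantile normalization and 1280 and 1480 with median centring; with a pseudocount of 1 the lower were 1041. At 4-fold, 416 and 111 became 1000 and 262 with a pseudocount of 1, 173 and 47 with 64, 208 and 196 with quantile normalization and 217 and 212 with median centring.

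The position of low-yield BIL 3, -0.06, changed sign with a pseudocount of 1 (0.00047), quantile normalization (0.14), median centring (0.038), the 8-fold difference (0.15) and the 8-fold difference with quantile normalization (0.28). The difference in position ranged from -0.14 (without low-yield BIL 3) to 0.28 (without low-yield BIL 2) when 1 line was left out (0.15 to 0.44 with quantile normalization), and was 0.026 with a pseudocount of 1. The correlation of the contrasts, 0.24, was 0.10 with no filter (9 of 10 splits as large; the cause was not tested) and ranged from -0.033 to 0.45 without the same lines, or -0.010 to 0.43 with quantile normalization; it was 0.14 without high-yield BIL 2 (0.16 with quantile normalization). Signals near background limit the dimmer probe sets: 36.7% to 53.8% of probe sets were under a signal of 16.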

Other observations

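The tests in this part were chosen after the results were seen, apart from the correlation with the parental contrast. Among the 404 probe sets at least 4-fold apart between the parents with quantile normalization, 169 had all 6 BILs nearer the high-yield parent and 2 had all 6 nearer the low-yield parent. Of the 169, 136 were higher in the high-yield parent and 33 higher in the low-yield parent. Low-yield BIL 3 alone was nearer the low-yield parent for 58 probe sets, and low-yield BILs 1 and 3 together for 40.

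A hypothesis was that a yield difference shared by lines and parents underlies the BIL differences. Of the probe sets at an unadjusted p under 0.05 and 2-fold between the BIL groups with quantile normalization, 86.1% had the sign of the parental difference, where the highest of the other splits gave 86.4%. On the deposited values the share was 85.7%, and the highest of the other splits gave 83.3%. In 2 of the 404 probe sets each BIL was nearer the parent of its own yield class, and another split gave 29. Lines share parental segments whatever their yield, so none of these values excludes the hypothesis or sets it apart.

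For the counts past the adjusted threshold, splits say nothing about chance, since each of the 10 splits of the BILs and each of the 35 splits with the parents gives at least the 0 of the yield groups (highest other 8383 and 7651). Over the 10 splits, too few for a share under 0.05, 4 gave at an unadjusted p under 0.05 and 2-fold at least 99 (highest other 5596), and 5 at least 101 with quantile normalization (highest other 1602). For the correlation with the parental contrast, 6 splits gave an r at least as far from 0 as 0.24 (highest other 0.49). With the parents, 12 of 35 splits gave at least the 232 at an unadjusted p under 0.05 and 2-fold (highest other 4617), and 9 at least 221 with quantile normalization (highest other 946), so chance is not excluded there.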
